A study of Mus musculus with 2 samples.

How the data were processed

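Droplet-based single-cell RNA sequencing had been run on live CD45+ cells sorted from B16 melanoma tumors of wild-type mice. The comparison was between tumors grown from cells with a short hairpin RNA against Sdc1 (shSdc1) and tumors grown from cells with a control hairpin (shRFP), as the sample titles give the groups. Each group was 1 library made from 6 pooled tumors. The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger 6.1.1 per the file headers, against the mouse genome build mm10 according to the submitters' processing notes. The annotation release is not given in the sources used here. The count tables held 31253 features for 5786 barcodes (shRFP) and 5902 barcodes (shSdc1), with 4255928 and 4370725 UMIs. Gene positions came from the GENCODE M21 annotation, which held 31107 of the features (99.5%) by identifier.

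A barcode was kept as a cell with at least 200 detected genes and under 10% of its UMIs from mitochondrial genes. In shRFP 530 barcodes had fewer genes and 46 had more mitochondrial UMIs, against 276 and 74 in shSdc1, some of them both, which left 5225 and 5576 barcodes. Doublets were scored with Scrublet, as run through scanpy, in each library. Its automatic threshold marked 3 and 5 barcodes (0.0574% and 0.0897%), too few for it to have worked, so the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes, 242 in shRFP and 263 in shSdc1. The 4983 and 5313 kept cells held 3859226 and 4016511 UMIs, with a median of 649 and 593 UMIs and of 425 and 403 genes per cell. The libraries shared 20 barcode sequences, and these were treated as separate cells.

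Both libraries were clustered together without integration, because library and group are the same thing here. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 highly variable genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1, with mitochondrial, ribosomal, immunoglobulin variable and T cell receptor variable genes left out. Of the 17 clusters, 16 received a class from marker lists fixed before the data were examined. The scoring rule was set after the data were seen. It took the class whose markers had the highest mean log2 fold in a cluster against other cells, required a mean of 0.5 and at least 3 markers at 2-fold, and tried clusters left without a name a second time against the cells of the other named classes. Monocyte and macrophage markers were joined in 1 class, as were B and plasma cell markers. A name was withdrawn where the 10 leading genes held more markers of another class than of its own, which left cluster 10, with the best score for monocytes and macrophages, without a name. T-like cells were clustered again with the same settings into 8 sub-clusters, of which 4 stayed without a name.

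UMIs were summed over the cells of a class in each library and given as CPM, the UMIs of a gene per 1000000 UMIs of these cells, with exact Poisson intervals. The ratio of CPM, shSdc1 over shRFP, has an exact conditional binomial interval, and shares of cells have exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only. A gene without a UMI in 1 library is given as a bound, computed against a floor of 3 counts in that library. The 21 gene lists were fixed before the data were examined. They covered cytotoxic effector, checkpoint and exhaustion, regulatory T, naive and memory T, type I interferon response, interferon gamma response, MHC class I, MHC class II, inflammatory myeloid, suppressive myeloid, complement and lipid macrophage, chemokine, proliferation, hypoxia and glycolysis, syndecan and heparan sulfate, and dissociation stress genes, with melanoma, red cell, fibroblast, endothelial and keratinocyte genes as lists of transcripts from cells outside the sort. A list was summarised by the median log2 ratio of its members with at least 20 UMIs in both libraries together, when at least 3 members had them. Its interval came from 1000 Poisson resamplings, and its percentile from 10000 random lists of equal size, each member drawn from the 100 genes nearest in expression. Members were drawn independently, while genes of a list can vary together. Such a list reaches an extreme percentile more readily, so the percentile is not a test. Of the listed symbols 1, Mx1, had no match in the files.

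Genes were named by a rule fixed before the data were examined. Among genes with at least 50 UMIs in both libraries together and a ratio of CPM of at least 1.5-fold either way, the 10 highest and 10 lowest were taken by the interval bound nearest to 1, for all kept cells and for classes with at least 200 cells in both libraries, which were the monocyte/macrophage-like and T-like classes. Mitochondrial, ribosomal, hemoglobin, immunoglobulin and T cell receptor genes, Xist, Y-linked genes and gene models without a name were left out of that ranking. List members could be named besides, when they were among the 2 to 4 members with the most UMIs of their list or had a ratio of at least 1.5-fold. Of the genes taken in monocyte/macrophage-like cells, 1 is not reported here. Shares of cells with a UMI were taken after thinning every cell to 300 UMIs and leaving out shallower cells.

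With 1 library per group no test was possible, and no p-value, standard error or count of changed genes is given. The calculation was tested on Poisson counts simulated from the summed counts. The ratio intervals held the true ratio for 95.2% to 96.9% of gene draws. Such counts leave out UMIs gathered in single cells, so this checks the arithmetic and not the spread of real cells. In all kept, monocyte/macrophage-like and T-like cells, 9%, 6% and 5.5% of simulated random lists lay outside the central 95% of percentiles. Of genes simulated without a difference, 1.97% in all kept cells, 2.99% in monocyte/macrophage-like cells and 5.38% in T-like cells lay past 1.5-fold, and of genes simulated at 2-fold, 93.2%, 91.4% and 82.0% did. The 30 alternatives chosen before the data were examined varied the cell filters, doublet removal, clustering, cell naming, scaling, the UMI minimum and the way cells were summed. Another 9 were added afterwards. They varied the naming score (0.25 and 1.0, which gave the same classes) and the Leiden seed, clustered without listed genes, weighted clusters alike in both libraries, left out the cell with the most UMIs of a gene, and left out cells with a UMI of Hspa1a or Hspa1b. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM scaling.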

Results

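Single-cell RNA sequencing was performed on live CD45+ immune cells sorted from subcutaneous tumors of the mouse melanoma line B16. Wild-type mice had been vaccinated with irradiated B16 cells that make GM-CSF, and 12 days later they received B16 cells carrying a hairpin RNA against Sdc1, the gene of the cell surface proteoglycan syndecan-1, or a control hairpin. After 16 days 6 tumors per group were pooled, and 1 library per group was made, so there are no replicates and the differences below were not tested. Genes and cell types are called higher or lower by the size of the difference, and the 95% intervals in brackets cover counting error only, not the spread between mice, tumors or libraries. A genotype label calls the shSdc1 sample a knockout, while its title and the protocol describe a hairpin in the injected cells. The shRFP library held 4983 kept cells with 3859226 UMIs (median 649 per cell) and the shSdc1 library 5313 kept cells with 4016511 UMIs (median 593 per cell).

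The gene targeted in the tumor cells was low in the sorted immune cells of both groups. Sdc1 (ENSMUSG00000020592, mm10 chromosome 12, 8771323 to 8793715, plus strand) had 101 UMIs in shRFP and 80 in shSdc1, or 26.2 CPM [21.3 to 31.8] and 19.9 CPM [15.8 to 24.8], a ratio of 0.761 [0.560 to 1.03]. Monocyte/macrophage-like cells held 99 and 64 of these UMIs. The sort keeps host cells, so this value does not measure the knockdown. Transcripts of the melanoma list were few, at 74.1 CPM in shRFP and 96.6 CPM in shSdc1. Their ratio of 1.30 [1.12 to 1.52] was 1.81 [1.58 to 2.09] over all barcodes. Most of their UMIs were from Mitf (130 and 103) and Syngr1 (116 and 232), while the pigment genes Pmel, Mlana, Tyrp1 and Dct each had at most 19 UMIs in either library. In monocyte/macrophage-like cells 3 genes of the list were measured, Syngr1 at a ratio of 2.60, Dct at 3.57 and Mitf at 1.01. Their median log2 ratio of 1.38 [0.57 to 1.71] is the value of Syngr1. No gene of the list was measured in T-like, NK-like or conventional DC-like cells. The Syngr1 and Mitf UMIs need not come from tumor cells, so this median does not measure tumor RNA. Other lists for cells outside the sort had few UMIs, with 1 and 2 of red cell, 7 and 8 of fibroblast and 6 and 17 of keratinocyte genes. Endothelial genes had 116 and 119 UMIs. Of that list 2 members were measured in monocyte/macrophage-like cells and 1 in T-like cells, so these UMIs need not come from endothelial cells.

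The question behind the comparison is how lowering syndecan-1 in the tumor cells relates to the anti-tumor immune response. T-like and NK-like cells made up a larger part of the sorted cells from shSdc1 tumors and monocyte/macrophage-like cells a smaller part. T-like cells were 21.5% [20.3 to 22.6] of kept cells in shRFP and 32.7% [31.5 to 34.0] in shSdc1, 1.52-fold higher [1.41 to 1.65]. NK-like cells were 1.67% [1.33 to 2.06] and 4.86% [4.29 to 5.47], 2.92-fold higher [2.27 to 3.78]. Monocyte/macrophage-like cells were 59.8% [58.4 to 61.2] and 46.5% [45.1 to 47.8], a ratio of 0.777 [0.736 to 0.820]. Among cells outside the monocyte/macrophage-like class the T-like ratio was 1.14 [1.06 to 1.24] and the NK-like ratio 2.19 [1.70 to 2.84]. Conventional DC 2-like cells, dendritic cells that mainly present antigen to CD4 T cells, were lower at 5.30% and 3.69%, a ratio of 0.696 [0.576 to 0.841].

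Other classes differed less or were small. Conventional DC 1-like cells, which cross-present antigen to CD8 T cells, were 2.81% in shRFP and 3.05% in shSdc1, and migratory DC-like cells 2.83% and 2.90%. B and plasma-like cells were 2.33% and 1.52%, a ratio of 0.655 [0.487 to 0.877] that was 1.45 with at least 500 genes per cell and 1.001 with every cell thinned. Plasmacytoid DC-like cells were 0.562% and 0.640%, and neutrophil-like cells 0.642% and 0.489%. Cluster 10, led by Retnla, Lyz1, Ear2 and Mgl2, held 2.59% and 3.65% of cells. It scored best for the monocyte/macrophage-like class but was kept out of it by the rule on leading genes, which was set after the data were seen. Its boundary depends on the clustering. With another Leiden seed a Retnla-led cluster without a name held 6.56% and 4.82% of cells. Clustered without the stress and hypoxia lists, such a cluster held 3.69% and 4.12%. Shares are of sorted CD45+ cells and say nothing of absolute numbers. The monocyte/macrophage-like ratio lay between 0.489 and 0.887 over the alternatives, and it was lowest with Scrublet's automatic threshold, where a C1q-led cluster of 582 and 1243 cells had no name. The NK-like ratio lay between 2.09 and 3.92.

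**Figure D1:**
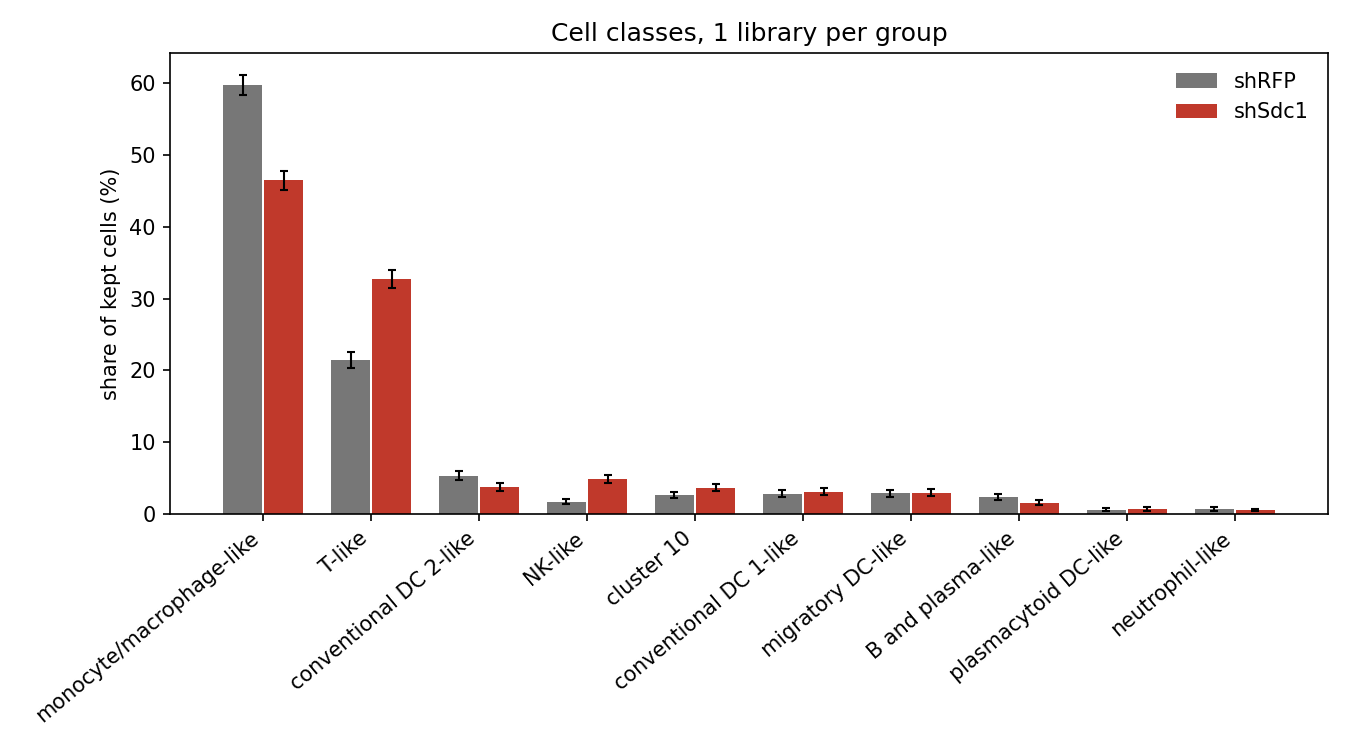
Shares of kept cells (%) per class in the shRFP and shSdc1 libraries, with exact 95% binomial intervals as error bars. T-like cells stand at 21.5% and 32.7%, NK-like cells at 1.67% and 4.86%, and monocyte/macrophage-like cells at 59.8% and 46.5%.

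T-like cells from shSdc1 tumors had a smaller naive-like share, and the regulatory-like, CD8-like and cycling-like shares were larger. These shares add up to all T-like cells, so a smaller naive-like share by itself raises the others. The larger regulatory-like and CD8-like shares thus need not be separate gains. In cells, the naive-like sub-cluster held 373 and 231, the regulatory-like 335 and 670, and the CD8-like 231 and 510. Shares without the naive-like cells were not computed. The naive-like sub-cluster was 34.9% [32.0 to 37.8] of T-like cells in shRFP and 13.3% [11.7 to 15.0] in shSdc1, a ratio of 0.381 [0.322 to 0.450] that was 0.391 when cells were clustered without any listed or marker gene. Regulatory-like cells were 31.3% and 38.6% (1.23-fold [1.08 to 1.41], but 1.12-fold [0.959 to 1.31] in that clustering), CD8-like cells 21.6% and 29.3% (1.36-fold [1.16 to 1.59]), and cycling-like cells 6.64% and 11.9% (1.78-fold [1.36 to 2.37]). Of all kept cells, CD8-like cells were 4.64% and 9.60%, and regulatory-like cells 6.72% and 12.6%. The shares of T-like cells with a UMI of Cd8a at 300 UMIs per cell were near each other, at 9.65% and 9.87%. Those for Foxp3 were 5.01% and 5.53%. Cd8b1 was also a leading gene of the Lef1-led T-like cluster 6, so the CD8-like sub-cluster need not hold all CD8 cells. The cycling-like cells had median UMI counts of 1201 and 1411.5, far above other T-like cells, so they can hold doublets. Sub-clusters 4 to 7 had no name and held 2.25%, 1.31%, 1.59% and 0.374% of T-like cells in shRFP and 3.80%, 2.42%, 0.345% and 0.403% in shSdc1. Sub-cluster 6, with 17 and 6 cells, was led by MHC class II and macrophage genes, among them H2-Aa, H2-Eb1, C1qa and C1qb. The regulatory-like sub-cluster was led by Areg and Klrg1 beside Foxp3 and Ikzf2.

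**Figure D2:**
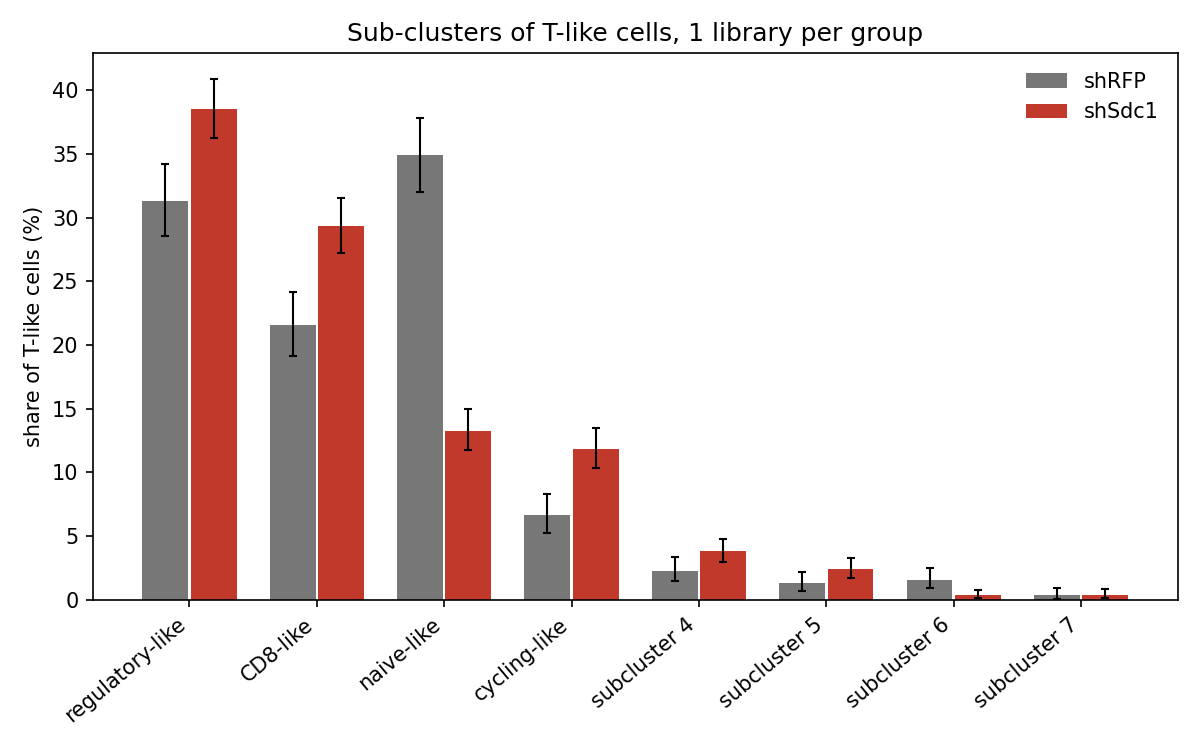
Shares of T-like cells (%) in each sub-cluster for both libraries, with exact 95% binomial intervals as error bars. The naive-like share is 34.9% in shRFP and 13.3% in shSdc1, while the regulatory-like, CD8-like and cycling-like shares are higher in shSdc1.

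Genes of naive and memory T cells were lower together in shSdc1 T-like cells, which describes the same cells as the smaller naive-like sub-cluster. Of 9 measured members 8 were lower by at least 1.5-fold, with a median log2 ratio of -1.29 [-1.55 to -0.98], below all 10000 random lists. The transcription factors Lef1 and Tcf7 had ratios of 0.279 [0.207 to 0.374] and 0.339 [0.226 to 0.504], Klf2, a regulator of T cell trafficking, 0.310 [0.239 to 0.401], and the lymph node homing gene Ccr7 0.430. Proliferation genes were higher, with a median of 0.47 [0.32 to 0.53] over 16 members, 3 of them by at least 1.5-fold (Top2a 1.71, Ccnb2 1.61, Mcm6 1.59). With clusters weighted alike the naive and memory median was -0.53 and the proliferation median 0.22, and with at least 500 genes per cell they were -0.46 and 0.25.

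Effector, checkpoint and regulatory lists showed small medians over T-like cells. The cytotoxic effector median was 0.15 [-0.04 to 0.28] with 3 of 17 members higher by at least 1.5-fold and 1 lower, and the median was -0.07 with at least 500 genes per cell. Tbx21, a master regulator of type 1 immunity, had a ratio of 2.14 [1.25 to 3.89], Fasl 2.02 and Ccl5 1.39, while the perforin gene Prf1 was lower at 0.523 [0.391 to 0.699]. Gzmb and Nkg7 had ratios of 1.22 and 1.11. The checkpoint and exhaustion median was 0.06 [-0.10 to 0.21] and turned to -0.31 with at least 500 genes per cell and -0.21 with clusters weighted alike. Of its 11 members only Entpd1, at 1.96, lay past 1.5-fold, and Pdcd1, which encodes PD-1, had a ratio of 0.9498. The regulatory T median was 0.17 [0.09 to 0.32] with 2 of 8 members higher, Il2ra at 1.54 and Izumo1r at 2.003, and it was -0.07 with clusters weighted alike. Type I interferon response genes had a median of 0.14 [-0.02 to 0.63] over 13 members (0.74 over genes with at least 100 UMIs), 5 of them higher by at least 1.5-fold (Isg15 1.91, Isg20 1.73, Ly6a 1.67, Oas3 1.66, Ifi27l2a 1.59) and Ifit2 lower at 0.325.

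The shares of T-like cells with a UMI of Cd8a at 300 UMIs per cell were near each other, 9.65% [7.74 to 11.9] in shRFP and 9.87% [8.37 to 11.5] in shSdc1. Cd4 was seen in 2.03% [1.18 to 3.22] and 4.62% [3.59 to 5.84], and Foxp3, the lineage factor of regulatory T cells, in 5.01% [3.63 to 6.71] and 5.53% [4.40 to 6.84]. These rest on 839 and 1429 cells, with 230 and 309 shallower cells left out. Without thinning, at median depths of 394 and 435.5 UMIs, the shares were 16.1% and 16.3% for Cd8a, 4.58% and 6.90% for Cd4, and 6.74% and 9.09% for Foxp3. In monocyte/macrophage-like cells, as background, shares at 300 UMIs were at most 0.259% (Cd4 in shSdc1), and unthinned shares at most 0.526% at median depths of 718 and 664.5 UMIs. Summed Cd4 UMIs gave a CPM ratio of 1.32 [0.955 to 1.83].

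The naming rule took 20 genes among 4749 in T-like cells. Higher in shSdc1 were Ccl1, a chemokine (2.80-fold [1.98 to 4.05], with 38.5% of the shRFP UMIs and 13.5% of the shSdc1 UMIs in 1 cell), the integrin gene Itgb1 (2.35-fold [1.83 to 3.04]), Matk, Bola3, H1f4, Smg6, Plk1, Sytl2, Pacsin2 and Izumo1r, with ratios from 2.003 to 3.52. Lower were Dapl1 (0.187 [0.101 to 0.331]), Lef1, Klf2, Hspa1a (0.363 [0.306 to 0.431]), Satb1, Tcf7, Klf3, Rhob, Txk and Jun (0.424). Of these Hspa1a and Jun are in the dissociation stress list, whose median was -0.32 [-0.53 to -0.21] in T-like cells, with 8 of 18 members lower by at least 1.5-fold. MHC class II genes (median -0.78 over 6 members) and complement and lipid macrophage genes (-0.74 over 10) were also lower in T-like cells. C1qa, C1qb, H2-Aa and H2-Ab1 had 17 to 97 UMIs per library. These 4 genes were among the leading genes of T-like sub-cluster 6, which held 17 cells in shRFP and 6 in shSdc1. The 2 lower medians may thus come from such cells and need not describe T cells, which was not tested. The complement median in T-like cells was 0.13 without doublet removal and 0.06 with clusters made without listed genes and weighted alike.

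Remaining lists in T-like cells had medians of 0.12 for interferon gamma response (16 members), 0.11 for MHC class I (9 members, -0.00 with at least 500 genes per cell), -0.28 for inflammatory myeloid (5, but 0.05 without doublet removal), 0.16 for suppressive myeloid (4, but -0.66 with no minimum on UMIs), -0.16 for chemokines (9, but 0.01 with clusters made without listed genes and weighted alike), -0.05 for hypoxia and glycolysis (15) and -0.59 for syndecan and heparan sulfate genes (6). Iigp1, an interferon-inducible GTPase, was higher at 2.11 [1.25 to 3.76], and Ccl3 was lower at 0.502 [0.423 to 0.595]. No TMM, median-of-ratios or gene-restricted scaling turned the sign of a T-like list median.

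NK-like cells were more frequent in shSdc1, while their gene list medians went both ways. The comparison rests on 83 and 258 cells, and TMM and median-of-ratios scaling move all its ratios by 0.22 and 0.19 (log2). The cytotoxic effector median was -0.07 [-0.29 to 0.24] and 0.16 with TMM scaling, with 2 of 13 members higher by at least 1.5-fold and 2 lower. The granzyme genes Gzmb and Gzmc were higher at 1.76 [1.27 to 2.51] and 1.63 [1.32 to 2.03], and 1 shRFP cell held 57.7% of that library's Gzmc UMIs, so without the top cell of each library the Gzmc ratio was 3.28 [2.41 to 4.58]. Gzmf was seen only in shRFP, with all 38 UMIs in 1 cell. Ccl5 was lower at 0.630 [0.516 to 0.772]. The dissociation stress median was -0.22 [-0.54 to 0.03] over 14 members and 0.01 with TMM scaling, and the proliferation median was 0.43 [-0.03 to 0.91] over 10 members, but -0.24 with at least 500 genes per cell. Other NK-like medians were 0.13 for checkpoint and exhaustion (4 members, but -0.36 with no minimum on UMIs), 0.07 for interferon gamma response (8), 0.04 for MHC class I (8, but -0.35 with at least 500 genes per cell), -0.17 for chemokines (4, but 0.05 with TMM scaling), -0.20 for naive and memory T (4, but 0.02 with TMM scaling), -0.31 for complement and lipid macrophage (5, but 0.82 with at least 500 genes per cell) and 0.13 for hypoxia and glycolysis genes (9, but -0.04 without doublet removal). All 8 MHC class I genes lay within 1.5-fold.

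Monocyte/macrophage-like cells from shSdc1 tumors had more transcripts of complement and lipid handling genes and fewer of inflammatory myeloid and hypoxia genes. Of 13 complement and lipid macrophage genes 7 were higher by at least 1.5-fold and 1 lower, with a median log2 ratio of 0.62 [0.57 to 0.65], above all 10000 random lists. Apoe, which encodes a lipid transport protein, was at 4336 CPM in shRFP and 11526 CPM in shSdc1, 2.66-fold higher [2.60 to 2.72], and the complement genes C1qa, C1qb and C1qc were higher at 2.04, 1.80 and 1.96. Spp1, which encodes osteopontin, went the other way at 0.441 [0.423 to 0.459]. Of 13 inflammatory myeloid genes 6 were lower by at least 1.5-fold and 1, Cxcl9, higher, with a median of -0.48 [-0.66 to -0.24]. This median was -0.04 without doublet removal and 0.0048 with clusters weighted alike. Without doublet removal a C1q-led cluster (601 and 1281 cells) and an Hspb1-led cluster (368 and 113 cells) had no name. Medians of this class without doublet removal, here and below, thus rest on a different set of cells. Il1b was at 2486 CPM and 775 CPM (0.312 [0.295 to 0.330]), Ptgs2, the gene of a prostaglandin synthase, at a ratio of 0.358, Il1a at 0.398, Il6 at 0.439, Cd80 at 0.471 and Tnf at 0.653.

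The mix of clusters in this class differed between the libraries, and the ratios above describe that mix as well as the state of cells. Cluster 0 was the largest in both libraries, but only in shSdc1 did it hold most of the class. Cluster 0, led by Ccl8, C1qa, Stab1 and Apoe, held 20.8% of the class in shRFP and 54.1% in shSdc1. Cluster 4, led by the stress and hypoxia genes Hspb1, Ero1l, Vegfa and Hspa1a, held 20.2% and 9.96%. Cluster 5, led by Il1a, Ptgs2 and Il1b, held 19.9% and 5.18%, and cluster 7, led by Hp, Chil3 and Plac8, 19.2% and 4.01%. Clusters 2 and 13, led by Gdf15 and Gpnmb and by the interferon-induced genes Rsad2 and Ifit3, held 15.5% and 4.43% in shRFP and 21.2% and 5.59% in shSdc1. With clusters made without any listed gene and weighted alike in both libraries, the complement median was 0.29 and the inflammatory median -0.02.

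Interferon response and MHC class I genes were higher in shSdc1 monocyte/macrophage-like cells. The interferon gamma response median was 0.50 [0.29 to 0.60], with 7 of 18 members higher by at least 1.5-fold and none lower, and the type I interferon response median was 0.40 [0.25 to 0.54], with 7 of 19 higher and none lower. Cxcl9, a chemokine that draws activated T cells, was 2.76-fold higher [2.41 to 3.16], Iigp1 3.52-fold [2.30 to 5.54], and Irf7 1.58-fold, while Cxcl10 had a ratio of 0.851 [0.783 to 0.925]. MHC class I genes had a median of 0.54 [0.42 to 0.61], with 4 of 9 higher by at least 1.5-fold (B2m 1.58, Tap1 1.67, H2-Q7 1.54, Nlrc5 1.77). The MHC class II median was -0.02 [-0.11 to 0.08], but 0.24 without doublet removal and 0.38 with at least 500 genes per cell, with Cd74 at 0.939 and H2-Ab1 at 1.04. The suppressive myeloid median was -0.09 [-0.17 to 0.05], but 0.19 without doublet removal and 0.11 with clusters weighted alike. Of its 14 members 3 were higher and 5 lower, with Retnla, Stab1 and Trem2 higher at 12.8, 2.10 and 1.80 and Chil3, Il10 and Ccl24 lower at 0.153, 0.403 and 0.454.

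Chemokine, hypoxia and stress genes were lower in shSdc1 monocyte/macrophage-like cells. The chemokine median was -0.50 [-0.53 to -0.33], with 8 of 18 members lower and 4 higher by at least 1.5-fold. Cxcl2 and Cxcl3, which attract neutrophils, had ratios of 0.455 and 0.436 and Ccl3 0.532, while Ccl8 was 5.26-fold higher [4.81 to 5.75] and Cxcl16 1.72-fold. The hypoxia and glycolysis median was -0.42 [-0.48 to -0.36], with 5 of 16 members lower by at least 1.5-fold (Egln3 0.479, Hif1a 0.4996, Ero1l 0.515, Slc2a1 0.592, Eno1 0.606) and none higher, and the median was -0.09 without doublet removal and -0.20 with clusters weighted alike. The dissociation stress median was -0.67 [-0.72 to -0.61], with 10 of 18 lower and none higher, among them Hspa1a at 0.414 and Hspa1b at 0.434, and the median was -0.39 without doublet removal and -0.23 with clusters weighted alike. Proliferation genes had a median of 0.41 [0.22 to 0.51] that was -0.24 with clusters weighted alike, -0.16 with clusters made without listed genes and weighted alike, and -0.02 with at least 500 genes per cell. Syndecan and heparan sulfate genes had a median of 0.18 [-0.09 to 0.41], but -0.02 over genes with at least 100 UMIs, with Sdc3 at 1.55 and Sdc4 at 1.001. The cytotoxic effector median was 0.58 [-0.51 to 0.75] over 5 members, 2 of them higher and 1 lower by at least 1.5-fold, while the chemokine gene Ccl4, with 7513 and 4056 UMIs the most abundant of them, had a ratio of 0.679. Other T cell lists had medians of -0.25 for checkpoint and exhaustion, -1.31 for regulatory T and -0.46 for naive and memory T genes, the regulatory T median being 0.29 with no minimum on UMIs and the naive and memory T median 0.07 without doublet removal.

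The naming rule took 20 genes among 7089 in monocyte/macrophage-like cells. Highest in shSdc1 were Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted product of alternatively activated macrophages, with 12 and 122 UMIs in only 7 and 36 cells (12.8-fold [7.07 to 25.4]), Ctsk (7.22-fold [5.10 to 10.5], and 5.24-fold without the top cell of each library), and Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799). Apoe, Ms4a7 (2.62), Parp11 (4.81), Cxcl9, Serpina3g (3.60), Pltp (2.66) and Iigp1 followed. Lowest were Nrg1 with 63 and 2 UMIs (0.0400 [0.00474 to 0.15045]) and Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like protein gene of inflammatory monocytes, with 468 and 71.8 CPM. Hp (0.152), Vcan (0.166), Slpi (0.226), Il1r2 (0.174), Spint1 (0.185), Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) and Fn1 (0.303 [0.277 to 0.331]) followed. TMM and median-of-ratios scaling moved all ratios of this class by -0.08 and -0.11 (log2), and all 20 genes were named again under both.

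**Figure D3:**
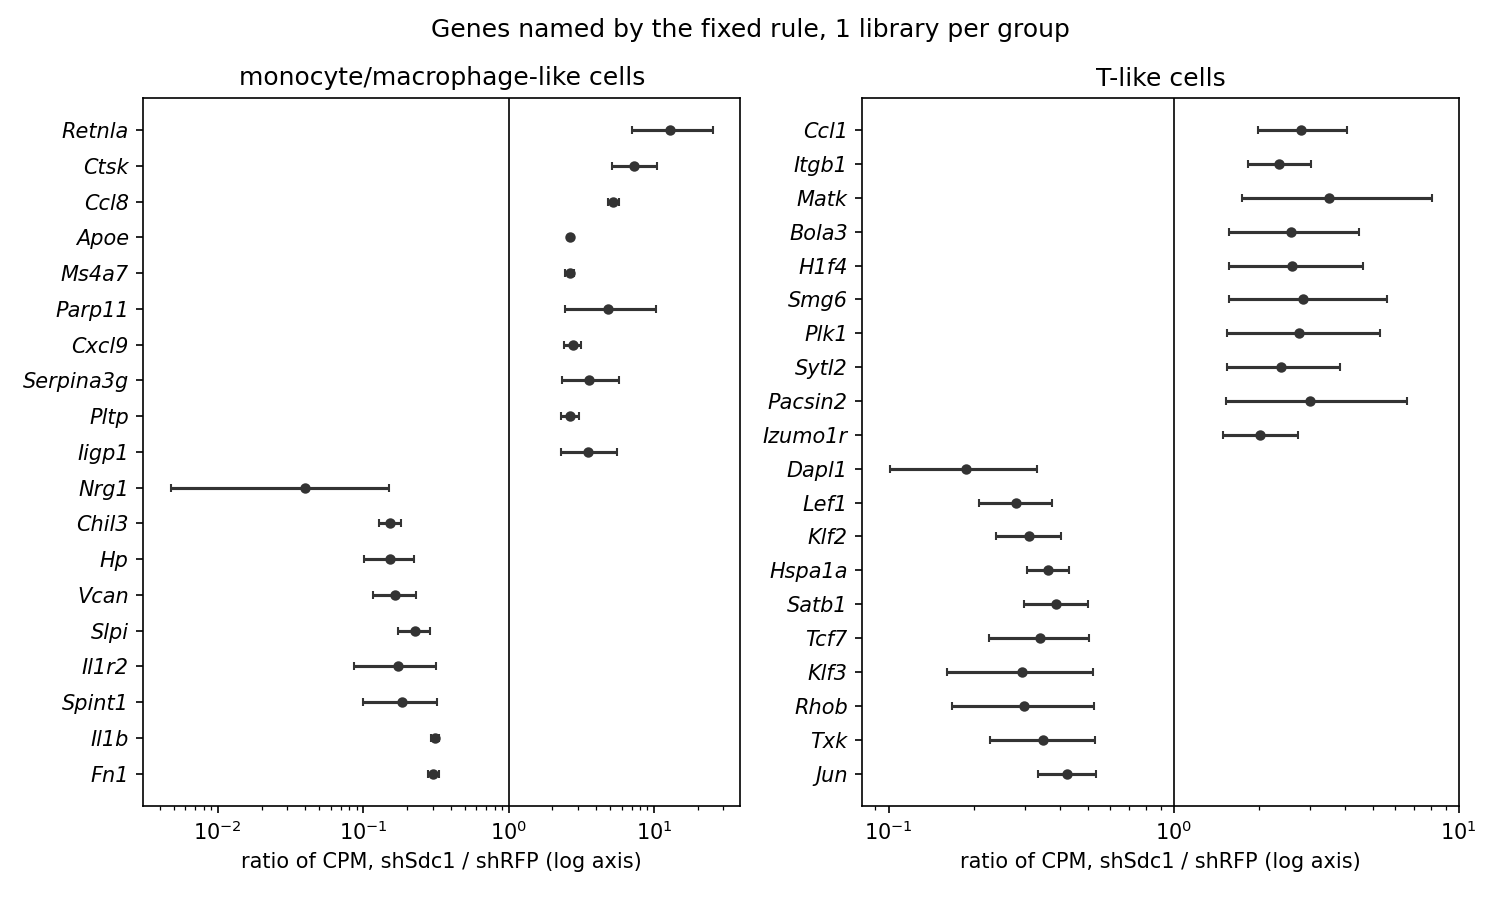
Ratios of CPM, shSdc1 over shRFP, on a log axis with 95% counting intervals, for 19 of the 20 genes taken by the rule in monocyte/macrophage-like cells and the 20 in T-like cells. Retnla stands highest at 12.8 and Nrg1 lowest at 0.0400 in monocyte/macrophage-like cells, and Dapl1 is lowest in T-like cells at 0.187.

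**Figure D4:**
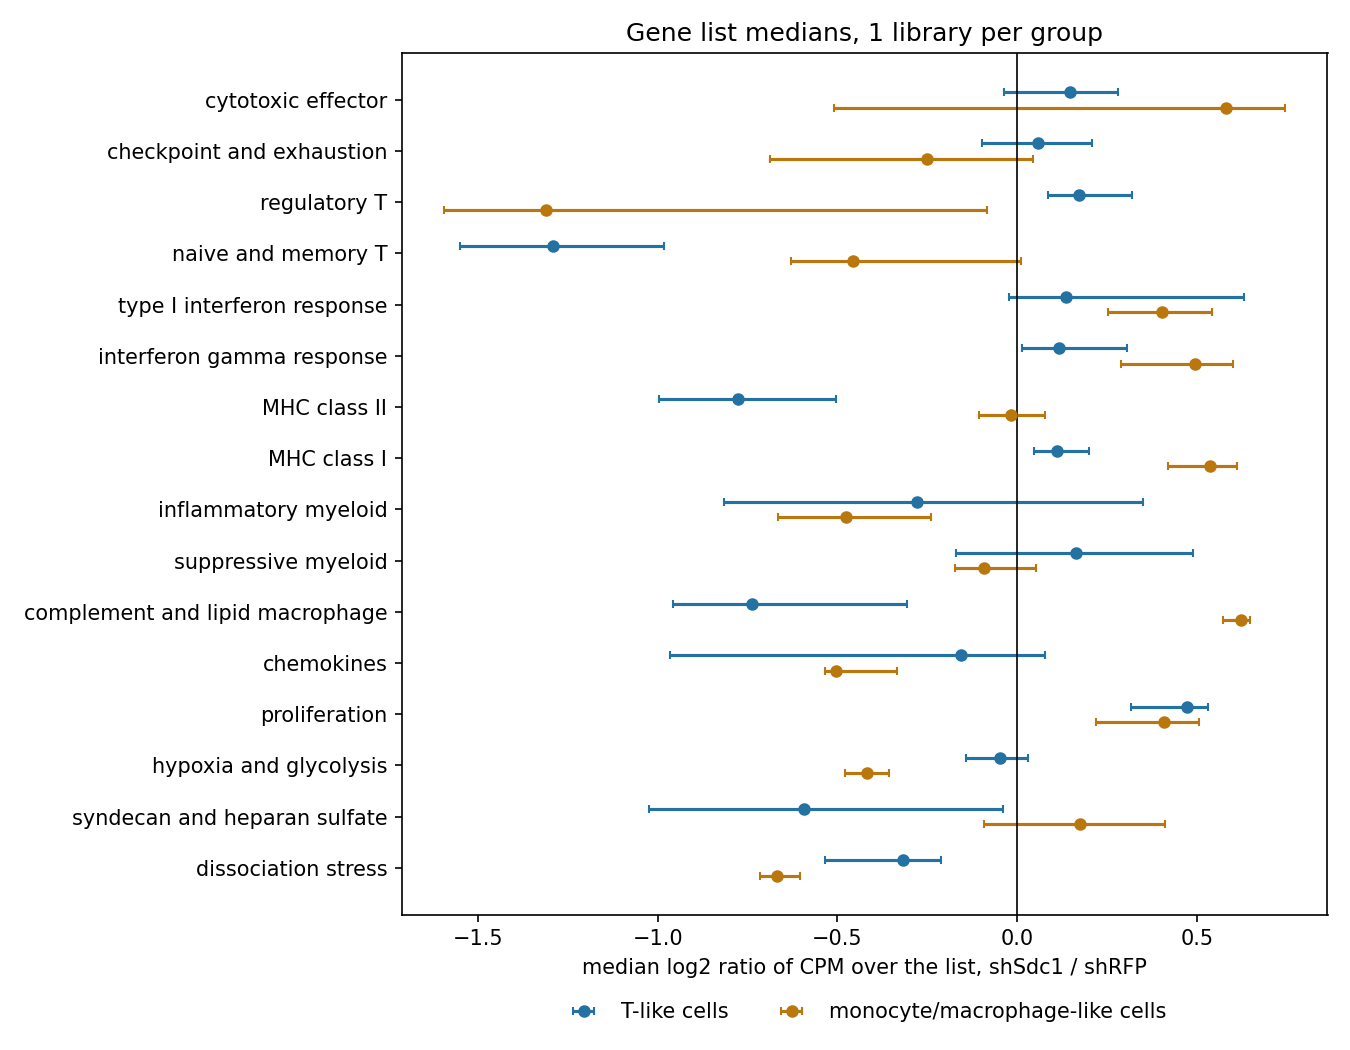
Median log2 ratio of CPM, shSdc1 over shRFP, for the gene lists in T-like and monocyte/macrophage-like cells, with 95% intervals from Poisson resampling. The naive and memory T list stands at -1.29 in T-like cells, and in monocyte/macrophage-like cells the complement and lipid macrophage list stands at 0.62 and the dissociation stress list at -0.67.

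Chemokine genes were lower in shSdc1 in conventional DC 2-like and migratory DC-like cells, and interferon response genes were higher in conventional DC 1-like cells. In conventional DC 1-like cells (140 and 162 cells) type I interferon response genes had a median of 0.97 [0.60 to 1.80] over 7 members, 5 of them higher by at least 1.5-fold, with Isg15 at 4.60 [2.35 to 10.1] and Irf7 at 2.92. Interferon gamma response genes had a median of 0.52 [0.21 to 0.99] over 9 members, with Cxcl9 at 3.36 [1.90 to 6.31] and Cxcl10 at 6.29 [2.25 to 24.4]. Their chemokine median was -0.61 [-0.92 to 0.05] over 6 members, 3 of them lower and 2 higher by at least 1.5-fold. In conventional DC 2-like cells (264 and 196 cells) the chemokine median was -0.78 [-1.19 to -0.52], with 9 of 12 members lower by at least 1.5-fold, among them Ccl5 at 0.224 and Ccl17 at 0.533, and Ccl4 higher at 1.51. Hypoxia and glycolysis genes were lower there, with a median of -0.56 [-0.74 to -0.33] and 6 of 15 members lower by at least 1.5-fold. In migratory DC-like cells (141 and 154 cells) the chemokine median was -0.99 [-1.23 to -0.46], with Ccl17 at 0.309, Ccl22 at 0.505 and Ccl4 at 0.242. Type I interferon response medians were 0.15 [-0.26 to 0.34] in DC 2-like and 0.47 [-0.04 to 1.12] in migratory DC-like cells, and the difference between classes was not tested. The dissociation stress medians were -1.10, -0.44 and -0.61 in the DC 1-like, DC 2-like and migratory DC-like cells, and the MHC class II medians -0.06, -0.03 (but 0.08 without doublet removal) and 0.02 (but -0.03 with at least 500 genes per cell). Median-of-ratios scaling moved all migratory DC-like ratios by 0.19 (log2).

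Summed over all kept cells, the genes named by the rule followed both the composition and the states above. Higher in shSdc1 among 8839 ranked genes were the NK cell genes Gzma (3.34-fold [2.81 to 3.99]), Gzmc (4.84-fold, and 8.28-fold without the top cell of each library) and Ncr1 (6.85-fold [3.25 to 16.6]), the regulatory T cell gene Izumo1r (3.38-fold), and Retnla (6.98-fold, with 97 and 658 of its 109 and 792 UMIs in cluster 10), Ccl8 (4.01-fold), Ctsk (5.38-fold), Ccl1 (4.59-fold), Sytl2 (4.74-fold) and Mmp9 (5.59-fold, with 48.4% of its shSdc1 UMIs in 1 cell). Lower were Chil3 (0.117 [0.0974 to 0.138]), Vcan, Hp, Nrg1, Serpinb2, Inhba (0.237), Il1b (0.288 [0.274 to 0.302]), Upp1 and Clec4e (0.274). Gzmg had 155 UMIs in shRFP and 0 in shSdc1, at least 53.8-fold lower, and 99.4% of them came from 1 cell. Of 9 regulatory T genes 8 were higher by at least 1.5-fold, with a median of 0.996, and of 17 cytotoxic effector genes 13 were higher and 2 lower, with a median of 1.08. Checkpoint and exhaustion genes had a median of 0.73, proliferation genes 0.70, MHC class I genes 0.47, interferon gamma response genes 0.46, type I interferon response genes 0.29, and complement and lipid macrophage genes 0.27. Below 0 were dissociation stress genes (-0.77), chemokines (-0.68), inflammatory myeloid (-0.52), hypoxia and glycolysis (-0.43), naive and memory T (-0.26), suppressive myeloid (-0.24), MHC class II (-0.14) and syndecan and heparan sulfate genes (-0.11). TMM and median-of-ratios scaling moved all ratios by -0.14 and -0.13 (log2).

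Among genes kept out of the ranking, immunoglobulin genes had 809 CPM in shRFP and 4060 CPM in shSdc1. Of these UMIs 40.6% in shRFP and 16.6% in shSdc1 were in 1 cell. Igkc had 1638 and 10039 UMIs, with 50.3% of the shRFP UMIs and 17.2% of the shSdc1 UMIs in 1 cell. Igha had 0 and 426 UMIs, at least 136-fold higher, and 97.9% of them came from 1 cell. Mitochondrial genes made up 1.98% and 1.89% of UMIs, and ribosomal protein genes 14.5% and 15.5%. T cell receptor genes had 572 and 981 CPM, 1.71-fold higher [1.63 to 1.81]. Xist had 2437 and 2339 CPM, and no UMI of a Y-linked gene was seen in either library.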

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

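The lists, genes and barcodes in this part were singled out after their values were seen, because they go opposite ways in different cell classes or lie outside the cells compared above, and the difference between classes was not tested.

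Neutrophil-like cells from shSdc1 tumors had more chemokine transcripts, while monocyte/macrophage-like, conventional DC 2-like and migratory DC-like cells had fewer. The chemokine median log2 ratio was 0.76 in neutrophil-like cells (32 and 26 cells), against -0.50 in monocyte/macrophage-like, -0.78 in conventional DC 2-like and -0.99 in migratory DC-like cells. Cxcl2, which attracts neutrophils, had log2 ratios of 1.04 in neutrophil-like cells, -1.14 in monocyte/macrophage-like, -1.04 in T-like and -1.30 in conventional DC 2-like cells, and -1.13 in cluster 10. Ccl3, a chemokine that attracts leukocytes, had log2 ratios of 1.66, -0.91 and -0.99 in neutrophil-like, monocyte/macrophage-like and T-like cells. Ccl4 had 1.54 in neutrophil-like cells, -2.05 in migratory DC-like cells and -1.21 in cluster 10. TMM and median-of-ratios scaling move all neutrophil-like ratios by -0.32 and -0.45, which is less than each of its values here.

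Cxcl9, the interferon-induced chemokine, was higher in shSdc1 in monocyte/macrophage-like cells (1.46) and conventional DC 1-like cells (1.75), and lower in conventional DC 2-like cells (-1.86). Complement and lipid macrophage genes had medians of 0.62 in monocyte/macrophage-like cells, 0.77 in neutrophil-like cells, 0.47 in B and plasma-like cells and 0.34 in cluster 10, against -0.74 in T-like and -0.45 in conventional DC 2-like cells. The last 2 directions depend on the processing, with 0.13 in T-like and 0.39 in conventional DC 2-like cells without doublet removal. No explanation was tested.

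Among barcodes removed as doublets, melanoma transcripts were at 683 CPM [587 to 790] in shSdc1, above 73.9 CPM [44.5 to 115] in shRFP. They came to 181 UMIs in 18 barcodes against 19 UMIs in 19 barcodes. The melanocyte genes Dct, Pmel and Tyrp1 had 56, 44 and 33 UMIs in shSdc1 and 0, 0 and 1 in shRFP. Kept cells leave out these barcodes, while values over all barcodes, without doublet removal or with the automatic threshold can hold them. No explanation was tested.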

How the results depend on the processing

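Of the alternatives below, clusters weighted alike, clusters made without listed genes, cells free of Hspa1a and Hspa1b, the naming scores, the second seed and leaving out the top cell were added after the data were seen. T-like cells were higher in shSdc1 under all 16 alternatives for shares (1.37 to 2.21), as were NK-like cells (2.09 to 3.92), while monocyte/macrophage-like (0.489 to 0.887) and conventional DC 2-like cells (0.568 to 0.845) were lower. Naive-like T cells lay between 0.346 and 0.391, and CD8-like cells between 1.33 and 1.44. In monocyte/macrophage-like cells the MHC class I median lay between 0.42 and 0.57 and the interferon gamma response median between 0.39 and 0.58. Where no reason is given below, the cause was not tested.

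With at least 100 genes per cell the share ratios were 1.37 for T-like, 0.862 for monocyte/macrophage-like and 0.568 for conventional DC 2-like cells. With at least 500 genes, which keeps 3817 cells and gives no neutrophil-like or plasmacytoid DC-like value, they were 2.21 for T-like, 3.92 for NK-like, 0.842 for monocyte/macrophage-like, 1.40 for migratory DC-like and, reversed, 1.45 for B and plasma-like cells. A cluster with monocyte genes (203 and 35 cells) had no name there. T-like medians were then -0.070 for cytotoxic effector, -0.46 for naive and memory T, 0.25 for proliferation and, reversed, -0.0015 for MHC class I genes. Monocyte/macrophage-like medians were 0.56 for type I interferon response, 0.40 for complement and, reversed, -0.023 for proliferation, and the conventional DC 2-like complement median reversed to 0.23.

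Without doublet removal the monocyte/macrophage-like ratio was 0.518, and a C1q-led cluster (601 and 1281 cells) and an Hspb1-led cluster (368 and 113 cells) had no name. Over the cells left in that class, medians were 0.66 for type I interferon response, -0.040 for inflammatory myeloid and 0.66 for complement genes. Those for hypoxia and stress genes were -0.091 and -0.39. Complement medians reversed to 0.13 in T-like and 0.39 in conventional DC 2-like cells. The ratio was 0.489 with Scrublet's automatic threshold, 0.860 at resolution 2.0 and 0.863 with centred genes, settings that also left clusters without a name (311 and 84 cells at resolution 2.0, 292 and 96 with centred genes). Resolution 0.5 gave 0.845 for conventional DC 2-like cells. Thinning gave 1.66 for T-like and 1.001 for B and plasma-like cells, the latter reversed, and no conventional DC 1-like value. Naming each cell by its highest marker score gave 2.09 for NK-like and 0.887 for monocyte/macrophage-like cells.

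With clusters weighted alike, and with those made without any listed gene weighted alike, T-like medians were -0.069 and -0.027 for regulatory T (both reversed) and 0.22 and 0.29 for proliferation genes. The first gave -0.53 for naive and memory T genes, and the second 0.058, reversed, for complement. In monocyte/macrophage-like cells they were 0.0048 (reversed) and -0.023 for inflammatory myeloid, 0.14 and 0.29 for complement, -0.24 and -0.16 for proliferation (both reversed), -0.20 and -0.24 for hypoxia, and -0.23 and -0.33 for stress genes. By construction these settings remove what the mix of clusters adds.

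Over cells with no UMI of Hspa1a or Hspa1b the stress medians were -0.20 in T-like and -0.59 in monocyte/macrophage-like cells, with 0.19, -0.70 and 0.67 in the latter for type I interferon response, inflammatory myeloid and complement genes. Complement, hypoxia and stress medians in that class were 0.54, -0.50 and -0.75 with TMM scaling and 0.51, -0.53 and -0.78 with median-of-ratios factors, which shift all genes alike. The mean over cells gave 0.71 for complement. With no minimum on UMIs the monocyte/macrophage-like regulatory T median reversed to 0.29 and the conventional DC 2-like checkpoint median to 0.23, and 12 and 6 of the 20 genes named in monocyte/macrophage-like and T-like cells were named again, because genes with few UMIs then enter. Over all barcodes the melanoma ratio was 1.81.

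Of 838 list medians under alternatives 708 stayed within their interval, as did 126 of 144 shares, 11 of 11 T-like subset shares and 358 of 378 gene ratios. Another 85 list medians, 1 share and 20 gene ratios not listed in this part moved without reversing. Depth limits what can be seen: of genes simulated at 2-fold, 82.0% in T-like cells lay past 1.5-fold, against 91.4% in monocyte/macrophage-like cells, and smaller classes were not simulated.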

Other observations

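Of the tests in this part, those on handling, on fewer monocytes and macrophages, on cells without Hspa1a or Hspa1b and on the inflammatory list by itself were chosen after the result was seen. B and plasma-like cells from shSdc1 tumors (116 and 81 cells) had an MHC class I median log2 ratio of 0.33 [0.05 to 0.59], against a median of -0.34 over random lists of like expression. The MHC class II median was -0.50 [-0.69 to -0.32], with H2-Aa at a ratio of 0.648 and H2-DMa at 0.478, but random lists had -0.33, and 23.1% of them lay lower. Over all kept cells Ighm was 3.67-fold higher, with 33.6% of its shRFP UMIs and 20.8% of its shSdc1 UMIs in 1 cell. Jchain, which joins secreted antibody units, was 8.58-fold higher, but its UMIs were in only 4 and 16 cells. Of these UMIs 52.4% in shRFP and 24.4% in shSdc1 were in 1 cell. Stress genes had a median of -0.67 over 17 members, against -0.36 over random lists. TMM, median-of-ratios and gene-restricted scaling move all ratios of this class by 0.35, 0.30 and 0.34 (log2).

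Gene lists were also summarised in cluster 10 and in the neutrophil-like and plasmacytoid DC-like cells. Cluster 10 (129 and 194 cells) had more transcripts of suppressive myeloid genes, with a median of 1.21 [0.53 to 1.61], 4 of 8 members higher and 1 (Tgfb1, 0.621) lower by at least 1.5-fold. Among the higher were Retnla (5.26-fold [4.25 to 6.58]), Arg1, an arginine-degrading enzyme (3.80-fold), and Il4ra, a receptor chain for interleukin-4 (3.88-fold). Its type I interferon response median was 1.05 [0.56 to 1.63], with Bst2 at 3.64 and Irf7 at 3.103, while Spp1 was lower at 0.216. These values hold for the main boundary of cluster 10 only. With another Leiden seed the Retnla-led cluster held 327 and 256 cells, and its lists were not summarised. Neutrophil-like cells (32 and 26 cells) had an inflammatory myeloid median of 0.69, with Tnf at 3.34 and Il1b at 1.54. Their MHC class II median was -1.87, with all 4 members lower and Cd74 at 0.168. TMM and median-of-ratios scaling move all ratios of neutrophil-like cells by -0.32 and -0.45 (log2), which takes up much of the inflammatory median. Plasmacytoid DC-like cells (28 and 34 cells) had a stress median of -1.70, with 7 of 8 members lower (Junb, with 27 and 2 UMIs, at 0.0723 [0.00834 to 0.288]), and an MHC class II median of -0.996.

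A lower dissociation stress list in shSdc1 was seen in several classes. RNA free in the droplets would give T-like cells little of it, since the highest T-like to monocyte/macrophage-like ratio of 4 abundant macrophage genes was 0.0255 in shRFP, while the stress list had 0.457, which argues against that source. A different mix of clusters is not the whole cause, as the monocyte/macrophage-like median with clusters weighted alike was -0.23 [-0.31 to -0.19]. A different mix of cells within clusters is not removed by this weighting and stays open. The median was under 0 in 9 of 9 classes with at least 10 measured members, although it was 0.01 in NK-like cells with TMM scaling. A difference in handling between the libraries and an effect of shSdc1 cannot be told apart, because each group was sorted and sequenced as 1 library.

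Larger T-like and NK-like shares and a smaller monocyte/macrophage-like share in shSdc1 were tested against depth and against a loss of 1 class. With every cell thinned and shallower cells left out, the T-like ratio was 1.66 [1.52 to 1.81]. Unequal depth of the cells left is thus not the whole cause. The filter on genes changed the size of the ratio, with 1.37 at 100 genes or more per cell and 2.21 at 500 or more. A part for depth and the filter stays open. If only monocytes and macrophages were fewer, all other classes would be higher by the same factor. Outside that class the NK-like ratio was 2.19 [1.70 to 2.84] and the conventional DC 2-like ratio 0.523 [0.432 to 0.631], so other classes differ too. Ratios there were 0.815 [0.646 to 1.03] for conventional DC 1-like, 0.769 [0.608 to 0.973] for migratory DC-like and 0.492 [0.366 to 0.659] for B and plasma-like cells. The T-like ratio was 1.14 [1.06 to 1.24], against 1.52 over all kept cells. Much of the larger T-like share thus goes with the smaller monocyte/macrophage-like share. Differences between the pooled tumors, in the sort, or from shSdc1 itself stay open and untested.

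More complement and fewer inflammatory transcripts in monocyte/macrophage-like cells may come in part from which cells were there. A stress response during handling stays open. Cells with no UMI of Hspa1a or Hspa1b had medians of 0.67 and -0.70 for the 2 lists, but their stress median was still -0.59, so leaving out the other cells did not remove the difference in stress genes. With clusters made without listed genes and weighted alike, the complement median was 0.29 [0.25 to 0.33]. It was 0.14 with the main clusters weighted alike. The mix of these clusters is thus not its whole cause, but this weighting cannot remove a different mix of cells within clusters. The inflammatory median was -0.023 [-0.18 to 0.13] with clusters made without listed genes, so the mix of clusters can account for that list. Clusters are made from expression and can follow the state of cells. This value thus cannot tell a different mix of cells from a change of state. An effect of shSdc1 on the state of these cells stays open and untested.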
